A study of Mus musculus with 24 samples.

How the data were processed

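RNA was measured in 24 libraries of mouse primary cortical astrocytes, 4 in each of 6 groups made of 2 genotypes (floxed control and IRKO) and 3 treatments (vehicle, 100 nM insulin, 100 nM IGF-1, each for 6 h after overnight serum starvation). Per the labels, the cells were used 5 days after infection with adenovirus, each library was made from 2 µg of RNA with an integrity number above 7, and poly-A libraries without strand information were read as 150 bp pairs. Genotype and virus go together in this design, since the floxed control cells received a virus without Cre. Groups and replicate numbers were taken from the sample titles.

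The deposited values are raw counts of reads per gene, 1 file per library, which the authors gave without normalization. The submitters' processing notes name STAR 2.7.7a, edgeR, DESeq2, R 4.0.4 and the mm10 genome without saying what each was used for. The counting program and the annotation release are not given in the sources used here. Each file held 32719 genes by Ensembl identifier and symbol, of which 23.4% had no count in any library. The last 3 lines of each file name no gene and were left out of library sizes and tests: they give the total reads (18731009 to 22365840), the reads overlapping genes and a count of the others that runs on from file to file. Reads outside genes, computed from the first 2 of these lines, were 14.5 to 23.2% of the total. The gene counts of a library summed to 4.55 to 4.93% more than its reads overlapping genes, so some reads were counted for more than 1 gene. Without strand information, reads of genes that overlap on opposite strands cannot be told apart, and genes that share over 20% of their exon length with another measured gene are given as uncertain. No mitochondrial genes were analysed here. Gene coordinates are 1-based on mm10 (GRCm38) from GENCODE M21, which held 32663 of the 32719 identifiers and 15587 of the 15599 tested. Replicates of a group differed by more than sampling noise in each pair (chi-square per gene 2.17 to 6.88), so each was kept as 1 library.

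Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with the edgeR expression filter (minimum count 10, minimum total 15), which left 15599, and libraries were scaled by TMM (factors 0.982 to 1.018). A quasi-likelihood model with 1 mean per group was fitted to all 24 libraries, so that the comparisons share 1 estimate of the spread, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 9 comparisons: insulin and IGF-1 against vehicle in each genotype, insulin against IGF-1 in each genotype, IRKO against floxed control under vehicle, and the difference between genotypes in each response. Levels are given as CPM, computed from the counts with TMM sizes, and log2 CPM used a prior count of 2. Library totals of 15429688 to 19010986 counts and a biological coefficient of variation of 4.9% set the precision, and errors of fold changes are standard errors of the fit.

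The 24 gene lists (538 entries) were fixed before the files were opened: autophagy initiation and phagophore, ATG8 family and conjugation, selective autophagy receptors and mitophagy, lysosome, FOXO targets, cholesterol synthesis and uptake, fatty acid synthesis, glucose uptake and glycolysis, ATF4 targets and amino acid supply, early response and MAPK feedback, ribosome biogenesis, cell cycle, insulin and IGF pathway, nuclear oxidative phosphorylation, circadian clock, p53 targets, interferon response, a reactive astrocyte panel, and markers of astrocytes, microglia, oligodendrocyte lineage, neurons, fibroblasts and mural cells, and endothelium. Lists share some genes. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01, which compares the list with all other genes, and again with the correlation estimated for each list. fry was run as an alternative and tests a different question, whether the genes of a list move one way on balance.

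Named genes were chosen by a rule fixed before the data were examined. In the comparisons with vehicle and in IRKO against floxed control, these were the 8 largest rises and the 8 largest falls among genes with adjusted p under 0.05, a mean log2 CPM of at least 2 and no overlap between the 4 libraries of one group and the 4 of the other. In insulin against IGF-1 it was 5 and 5 by the same rule, and for the differences between genotypes 5 and 5 without the overlap condition, which no gene met. Up to 4 members of each list with the lowest p were added, and always Insr, Igf1r, Irs2, Ulk1, Ulk2, Gabarapl1, Map1lc3b, Sqstm1, Bnip3, Tfeb, Foxo1 and Foxo3. Genes named outside this rule are said to have been chosen after their values were seen.

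Overlaps of comparisons that share vehicle libraries were set beside 20 simulations of unchanged groups against those libraries, independent lists, and the 6 splits of the vehicle libraries into 2 and 2. The fits were tested on simulated counts drawn from the real means and library sizes, 5 simulations with 200 changed genes each among 15599. For insulin against vehicle in the floxed control, edgeR recovered 45.4% of genes changed 1.2-fold, 73.7% of those changed 1.5-fold and 88.5% of those changed 2-fold, with 50 false calls among 741. For the difference between genotypes in the insulin response it recovered 21.8%, 62.7% and 80.9%, with 35 false calls among 585. DESeq2 1.42.0 recovered 47.5%, 74% and 87.9% in the first and 25.1%, 63.3% and 81.8% in the second. Of 50 simulated lists without change, camera called 0 at an unadjusted p under 0.05. Alternatives were RLE size factors, library size alone, DESeq2, no filter on low counts, a mean CPM of at least 1, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. For lists these were the estimated correlation, fry, the block and RLE factors, for the overlap the split vehicle libraries, an adjusted p under 0.01, the block and DESeq2, and for the response size an adjusted p under 0.01, the mean over genes and RLE factors. Leaving out the 5 libraries with over 20% of reads outside genes and a microglia marker score as a covariate were added after seeing the data, as were a mean log2 CPM of at least 2 and the comparisons of the genotypes under each ligand and over all treatments.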

Results

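Gene expression was measured in primary cortical astrocytes from newborn mouse pups that carried a floxed insulin receptor gene. Cultures infected with an adenovirus for green fluorescent protein kept the receptor gene (floxed control, IRflox), and cultures infected with an adenovirus for a Cre and green fluorescent protein fusion were the receptor knockouts (IRKO). After overnight serum starvation, each genotype was given vehicle, 100 nM insulin or 100 nM IGF-1 for 6 h. The 2 genotypes and 3 treatments made 6 groups of 4 libraries, 24 in all. Poly-A RNA was sequenced as pairs of 150 bp reads without strand information. The libraries held 15429688 to 19010986 gene counts, and 15599 of 32719 genes were abundant enough to be tested. Reads falling outside genes made up 14.5 to 23.2% of a library (median 17.6%). The biological coefficient of variation was 4.9%. The first principal component held 61.1% of the variance and separated the vehicle libraries from all treated ones, and the second held 9% and separated the genotypes. The labels do not say whether the 4 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

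The targeted gene, Insr, which encodes the insulin receptor, lies on chromosome 8 at 3122061 to 3279617 on the minus strand (mm10, GENCODE M21). Its level under vehicle was 61.6 ± 3.60 CPM (counts scaled to library size; SD, n = 4) in floxed control astrocytes and 40.4 ± 2.47 CPM in IRKO astrocytes. Under insulin the levels were 49.6 ± 2.35 and 29.0 ± 1.70 CPM, and under IGF-1 they were 48.5 ± 1.95 and 30.3 ± 1.40 CPM. IRKO libraries thus held 65.7% of the floxed control level under vehicle, 58.4% under insulin and 62.5% under IGF-1. The log2 differences were -0.61 (SE 0.055), -0.78 (SE 0.058) and -0.68 (SE 0.058), with adjusted p of 3e-10, 1.56e-12 and 1.17e-10 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Insr was lower in 12 of 12 IRKO libraries than in each floxed control library of the same treatment. The counts are summed over the whole gene, so exons outside the floxed part contribute to the remaining level, which is not the share of intact receptor transcripts. With a score of microglia markers as a covariate, chosen after seeing the data, the vehicle difference was -0.49 with an edgeR adjusted p of 0.053.

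Igf1r, which encodes the IGF-1 receptor (chromosome 7, 67952827 to 68233668, plus strand), did not pass the test between genotypes under vehicle, with 191.4 ± 2.00 CPM in floxed control and 200 ± 3.38 CPM in IRKO astrocytes (n = 4 each, log2 difference 0.06, SE 0.038, edgeR adjusted p = 0.351). Both receptor genes fell with treatment. In floxed control astrocytes Igf1r fell to 88.4 ± 3.37 CPM under insulin and 99.1 ± 2.57 CPM under IGF-1, and in IRKO astrocytes to 93.8 ± 3.85 and 103.8 ± 5.83 CPM. Insr changed with insulin by -0.31 (SE 0.054, edgeR adjusted p = 7.24e-06) in floxed control and by -0.48 (SE 0.059, 5.5e-09) in IRKO astrocytes.

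**Figure D1:**
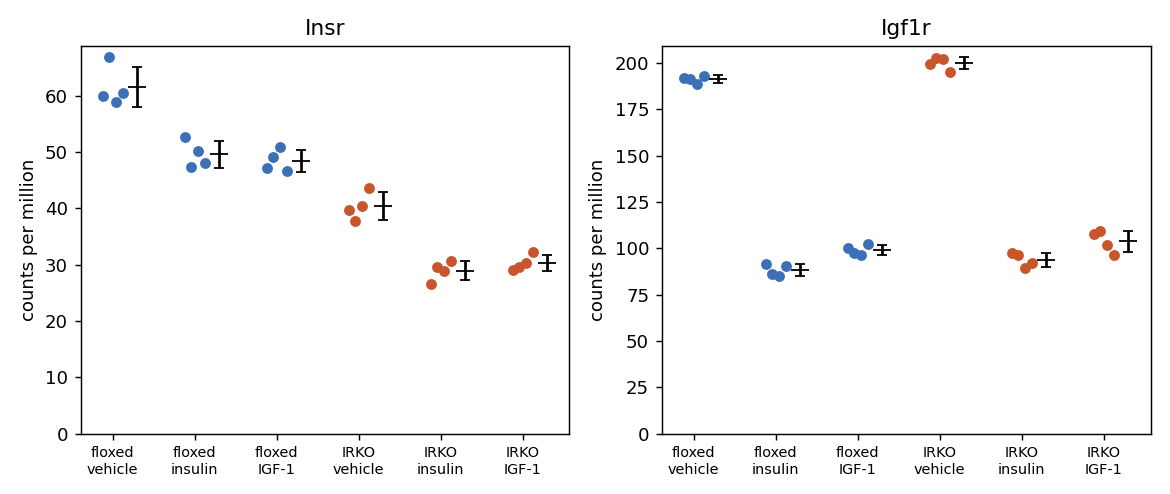
Insr and Igf1r levels in CPM in each of the 24 libraries (points), by genotype and treatment, with the group mean and SD in black. Insr lies lower in the IRKO libraries (orange) than in the floxed control libraries (blue) under each treatment, and Igf1r falls under insulin and IGF-1 in both.

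Whether insulin changes transcription in astrocytes with an intact receptor gene was answered by insulin against vehicle in the floxed control. Fbxo32, a muscle atrophy ubiquitin ligase gene driven by FOXO factors (chromosome 15, 58175879 to 58214932, minus strand), fell from 43.8 ± 2.53 to 4.71 ± 1.07 CPM (SD, n = 4 each). Ulk1, the kinase gene that starts autophagy (chromosome 5, 110784488 to 110810097, minus strand), fell from 99.4 ± 5.62 to 38.8 ± 2.52 CPM. Hsd17b7, a cholesterol synthesis gene (chromosome 1, 169949535 to 169969241, minus strand), rose from 40.1 ± 0.752 to 140.5 ± 9.67 CPM, and the tubulin gene Tuba8 (chromosome 6, 121210696 to 121226854, plus strand) rose from 3.95 ± 0.275 to 18.3 ± 1.59 CPM. In all, 7131 of 15599 genes changed (45.7%, edgeR, adjusted p under 0.05), 3798 upward and 3333 downward. A change of more than 1.5-fold was found for 616 of those that rose and 699 of those that fell. The balance of rises and falls turned with library size alone as the scaling (3490 upward, 3590 downward) and with a mean CPM of at least 1 (3401, 3662).

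The 8 largest rises were in Tuba8 (log2 2.20, SE 0.12), Apln, the apelin gene (1.81, SE 0.082), Hsd17b7 (1.81, SE 0.056), the lysolipid carrier gene Mfsd2a (1.69, SE 0.053), Idi1 of the mevalonate pathway (1.63, SE 0.057), Tnfrsf22 (1.58, SE 0.087), Rab27b (1.51, SE 0.102) and Ngef (1.51, SE 0.147). The 8 largest falls were in Fbxo32 (-3.22, SE 0.119), Ypel3 (-2.38, SE 0.084), Tmem140 (-2.15, SE 0.081), Tcp11l2 (-2.06, SE 0.073), Crebrf (-2.05, SE 0.061), Pdk4, a kinase gene whose product inhibits pyruvate dehydrogenase (-1.98, SE 0.165), C530044C16Rik (-1.94, SE 0.119) and Cyren (-1.89, SE 0.071). Tmem140 and Cyren share 37% and 50.8% of their exon length with each other, so their counts are uncertain.

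**Figure D2:**
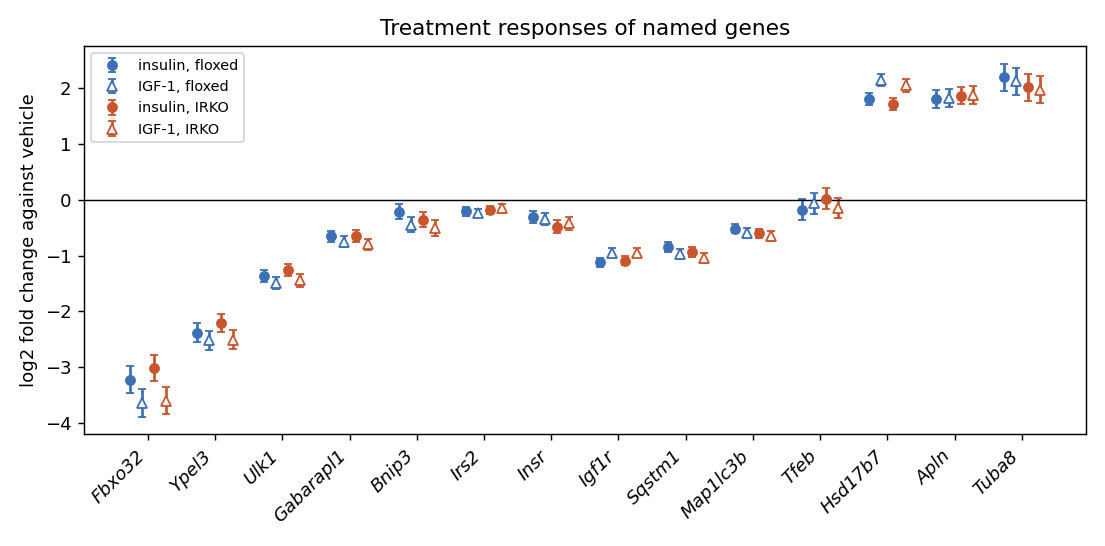
Log2 fold changes with 95% intervals of 14 genes in the 4 comparisons of insulin or IGF-1 with vehicle. Fbxo32, Ypel3, Ulk1 and Gabarapl1 lie below 0 and Hsd17b7, Apln and Tuba8 above 0 in each comparison, while Tfeb lies near 0.

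Autophagy genes fell in floxed control astrocytes given insulin. Of 22 genes of autophagy initiation and phagophore growth, 18 fell and 1 rose, with Ulk1 at -1.36 (SE 0.054), Zfyve1 at -1.004 (SE 0.05), Wipi1 at -1.03 (SE 0.061) and Ulk2 at -0.75 (SE 0.045), and the list stood below other genes (camera adjusted p = 5.6e-20). Wdr45 fell by 1.65 on the log2 scale, but shares 24.7% of its exon length with another gene. Among 16 genes of the ATG8 family and its conjugation, 5 fell and 3 rose. Gabarapl1 changed by -0.65 (SE 0.05), Map1lc3b by -0.51 (SE 0.042), Atg12 by -0.28 (SE 0.054) and Atg3 by 0.20 (SE 0.051), and the list as a whole did not pass (camera adjusted p = 0.15). Of 18 selective autophagy receptor and mitophagy genes, 10 fell and 3 rose (camera adjusted p = 7.3e-08). The cargo receptor gene Sqstm1 fell from 1324 ± 75.3 to 734 ± 35.5 CPM (n = 4 each), Calcoco1 changed by -1.36 (SE 0.047), Retreg1 by -1.02 (SE 0.062) and Bnip3 by -0.21 (SE 0.068). Of 30 lysosome genes 22 fell and none rose, among them Clcn7 (-0.50, SE 0.05), Mcoln1 (-0.61, SE 0.076) and the cholesterol exporter gene Npc1 (-0.34, SE 0.039). The camera adjusted p of the lysosome list was 1e-05, and adjusted p = 0.092 with an estimated correlation. Tfeb, a transcription factor for lysosome genes, did not pass (-0.18, SE 0.093, edgeR adjusted p = 0.125), though it did without IRflox vehicle replicate 4 (adjusted p = 0.015) or IRflox insulin replicate 2 (0.049). FOXO target genes fell in 27 of 32 cases and rose in 2 (camera adjusted p = 3.3e-32), with Pik3ip1 at -1.19 (SE 0.05). Foxo3 itself fell by 0.29 on the log2 scale (SE 0.038) and Irs2 by 0.21 (SE 0.038). Foxo1 rose by 0.18 (SE 0.057, edgeR adjusted p = 0.00902), a call lost without IRflox insulin replicate 1 (0.055).

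Lipid and biosynthetic genes rose. All 25 measured genes of cholesterol synthesis and uptake rose with insulin, by a median of 1.18 on the log2 scale (camera adjusted p = 4.9e-124), including Lss (1.44, SE 0.043), Cyp51 (1.30, SE 0.038) and Hmgcs1 (1.15, SE 0.036). Of 18 fatty acid synthesis genes 16 rose and 2 fell (median 0.82, camera adjusted p = 2.8e-40), with Scd1 at 1.08 (SE 0.033), Scd2 at 0.85 (SE 0.031), Fasn at 1.00 (SE 0.039) and Acaca at 1.04 (SE 0.042). All 26 ribosome biogenesis genes rose (median 0.64, camera adjusted p = 4.3e-31), for example Nop58 (0.95, SE 0.059), Ddx21 (0.79, SE 0.036) and Mybbp1a (0.60, SE 0.036). Genes of ATF4 targets and amino acid supply rose in 19 of 27 cases and fell in 2, with Psat1 of serine synthesis at 0.83 (SE 0.044) and the arginine carrier gene Slc7a1 at 0.83 (SE 0.058). That list had a camera adjusted p of 2e-05, and adjusted p = 0.096 with an estimated correlation. Glucose uptake and glycolysis genes rose in 12 of 18 cases and fell in 3, with Ldha at 0.47 (SE 0.037), and had a camera adjusted p of 0.0043, and adjusted p = 0.21 with an estimated correlation. Nuclear oxidative phosphorylation genes rose in 14 of 24 cases, with Cyc1 at 0.50 (SE 0.046), and had a camera adjusted p of 0.0046, and adjusted p = 0.42 with an estimated correlation.

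The other lists, except microglia markers, did not pass as a whole by camera. Insulin and IGF pathway genes rose in 9 and fell in 15 of 34 cases (camera adjusted p = 0.08). Early response and MAPK feedback genes rose in 6 and fell in 12 of 30, with Spry4 at 0.62 (SE 0.061), Klf2 at -0.89 (SE 0.115) and Dusp1 at -0.68 (SE 0.089) (camera adjusted p = 0.15). Circadian clock genes rose in 6 and fell in 7 of 16, with Nr1d2 at -0.85 (SE 0.04) and Arntl at 0.70 (SE 0.076) (camera adjusted p = 0.29). Interferon response genes rose in 15 and fell in 1 of 27 (camera adjusted p = 0.071), and p53 targets rose in 3 and fell in 6 of 16 (0.35). Genes of the reactive astrocyte panel rose in 9 and fell in 13 of 34 (camera adjusted p = 0.48), and cell cycle genes rose in 2 and fell in 2 of 31 (0.69). Among cell type markers, those of astrocytes rose in 6 and fell in 6 of 17 (camera adjusted p = 0.74), and oligodendrocyte lineage markers rose in 4 and fell in 1 of 10 (0.35). By the same test, neuron markers rose in 4 and fell in 1 of 10 (0.29), fibroblast and mural cell markers rose in 1 and fell in 1 of 11 (0.9), and endothelial markers fell in 1 of 6 (0.68). Microglia markers fell in 10 of 15 cases and none rose, with C1qa at -0.33 (SE 0.056) and Csf1r at -0.20 (SE 0.037), and had a camera adjusted p of 0.026, and adjusted p = 0.21 with an estimated correlation. Csf1r shares 15.1% of its exon length with an opposite-strand gene. Adjusted over the list alone, the counts differed only for lysosome (23 fell), ATF4 targets (20 rose), cell cycle (1 fell), insulin and IGF pathway (16 fell), oxidative phosphorylation (17 rose), interferon response (2 fell), oligodendrocyte lineage (3 fell) and fibroblast and mural cell markers (0 rose).

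**Figure D3:**
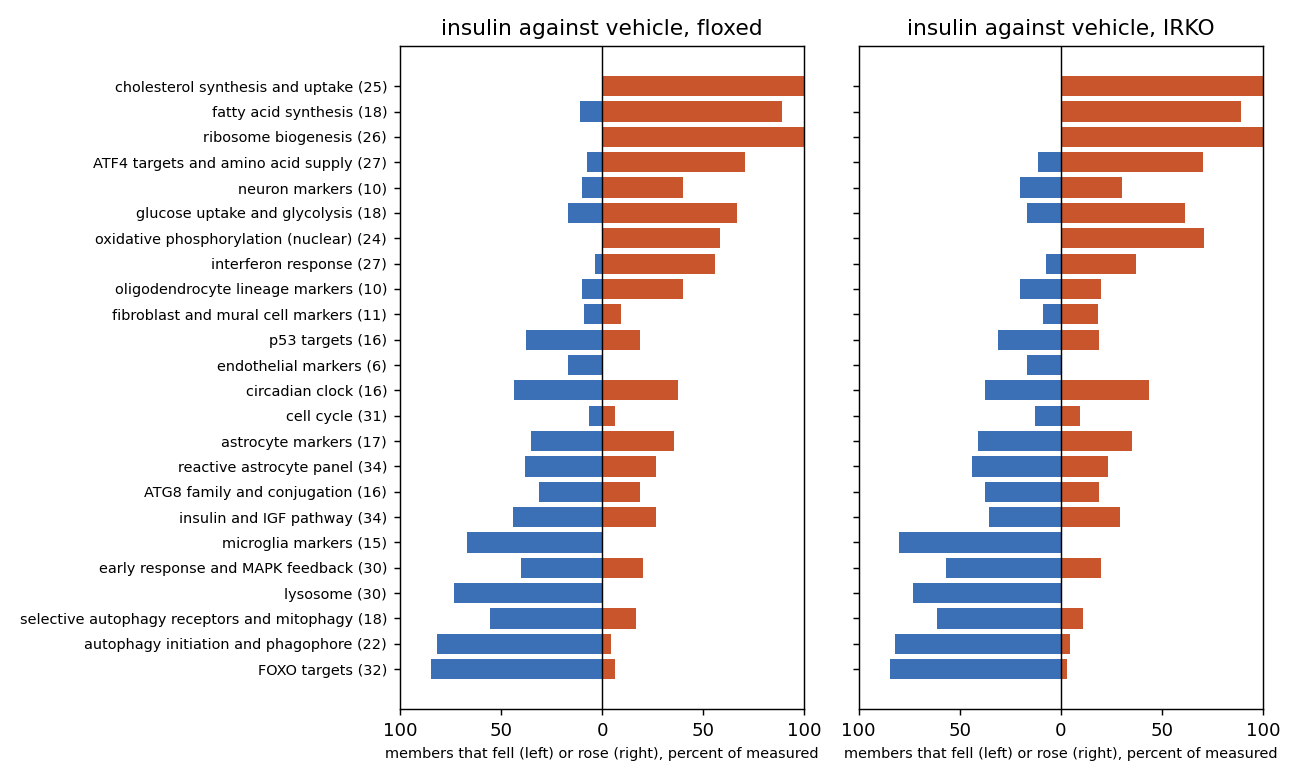
Percent of the measured members of each gene list that fell (left of 0) or rose (right of 0) under insulin against vehicle, in floxed control and IRKO astrocytes, with the number measured in brackets. Cholesterol synthesis and ribosome biogenesis genes rose in every case, and autophagy initiation, lysosome and FOXO target genes mostly fell.

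Traces of liver transcripts differed between libraries, within groups too. Alb, the serum albumin gene, had 0 to 2 counts in the floxed vehicle libraries, 50 to 153 under insulin and 1 to 57 under IGF-1, and 0 to 112, 1 to 133 and 7 to 38 counts in the IRKO groups under vehicle, insulin and IGF-1. These counts passed the test for insulin against vehicle in the floxed control (edgeR adjusted p = 2.15e-05). Alb lies outside the rule for named genes and was chosen after its values were seen.

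Whether IGF-1 acts on the same genes was asked first in the floxed control. IGF-1 lowered Fbxo32 to 3.52 ± 0.972 CPM and Ulk1 to 35.4 ± 1.91 CPM and raised Hsd17b7 to 178.5 ± 18.4 CPM and Tuba8 to 17.3 ± 1.53 CPM (SD, n = 4 each). In total 7930 genes changed against vehicle (50.8%, edgeR), 4121 upward and 3809 downward, with 853 and 908 of them past 1.5-fold. This balance turned too with library size alone (3890, 4061) and a mean CPM of at least 1 (3762, 4137). The 8 largest rises were in Hsd17b7 (2.15, SE 0.056), Tuba8 (2.13, SE 0.121), Mfsd2a (1.95, SE 0.053), the cytokine gene Tnfsf11 (1.90, SE 0.172), the growth factor gene Ereg (1.86, SE 0.17), Apln (1.83, SE 0.082), Rab27b (1.82, SE 0.1) and Prokr1 (1.81, SE 0.155). The 8 largest falls were in Fbxo32 (-3.63, SE 0.125), Ypel3 (-2.52, SE 0.085), Crebrf (-2.33, SE 0.063), Tcp11l2 (-2.25, SE 0.074), C530044C16Rik (-2.19, SE 0.122), Pdk4 (-2.16, SE 0.168), Tmem140 (-2.10, SE 0.08) and Pappa, a protease that frees IGF from its binding proteins (-1.93, SE 0.09).

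Under IGF-1 in the floxed control, autophagy initiation genes fell in 18 of 22 cases and rose in 1 (camera adjusted p = 3.2e-18), selective autophagy genes fell in 12 of 18 and rose in 2 (2.8e-08), and FOXO targets fell in 26 of 32 and rose in 1 (2.9e-30). Gabarapl1 fell by 0.74 on the log2 scale, Map1lc3b by 0.59, Sqstm1 by 0.97, Bnip3 by 0.44, Ulk2 by 0.87, Foxo3 by 0.42 and Irs2 by 0.23, while Tfeb (-0.06) and Foxo1 (0.01) did not pass. ATG8 family genes fell in 7 of 16 cases and rose in 3 (camera adjusted p = 0.093). Cholesterol synthesis genes rose in 25 of 25 cases (median 1.33, camera adjusted p = 3.2e-122), fatty acid synthesis genes in 16 of 18 (4.8e-33) and ribosome biogenesis genes in 26 of 26 (4.8e-33), with Lss at 1.70, Scd1 at 1.12 and Ddx21 at 0.86. Lysosome genes fell in 22 of 30 cases and rose in 1, with a camera adjusted p of 4.7e-05, and adjusted p = 0.13 with an estimated correlation. ATF4 targets rose in 19 and fell in 3 of 27 (camera adjusted p = 0.00011, and adjusted p = 0.15 with an estimated correlation). Glycolysis genes rose in 10 and fell in 1 of 18 (camera adjusted p = 0.0029, and adjusted p = 0.21 with an estimated correlation). Oxidative phosphorylation genes rose in 20 of 24 (camera adjusted p = 0.00053, and adjusted p = 0.26 with an estimated correlation). Of 16 p53 targets 8 fell and 2 rose, with Fas at -0.55 and Trp53inp1 at -0.47 (camera adjusted p = 0.039, and adjusted p = 0.26 with an estimated correlation). Early response genes rose in 11 and fell in 10 of 30 (camera adjusted p = 0.75), with Spry4 at 0.88 and Spred3 at 0.66. Microglia markers fell in 7 of 15 cases (camera adjusted p = 0.13). Adjusted over the list alone, 27 FOXO targets fell, and the counts of the other lists named here were the same.

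In IRKO astrocytes insulin was compared with vehicle to ask what remains of the response when the receptor transcript is lower. Fbxo32 fell from 49.4 ± 2.83 to 6.10 ± 0.846 CPM, Ulk1 from 98.2 ± 5.48 to 41.3 ± 2.12 CPM and Sqstm1 from 1302 ± 66.4 to 678 ± 18.6 CPM, and Hsd17b7 rose from 51.1 ± 2.80 to 168.3 ± 5.57 CPM (SD, n = 4 each). By edgeR 7239 genes changed (46.4%), 3852 upward and 3387 downward (3629 and 3638 with library size alone), with 697 and 654 past 1.5-fold. The 8 largest rises were in Tuba8 (2.02, SE 0.118), Apln (1.87, SE 0.078), Hsd17b7 (1.72, SE 0.054), Mfsd2a (1.70, SE 0.053), Ngef (1.61, SE 0.156), the lipase gene Pnpla3 (1.51, SE 0.138), Prr7 (1.49, SE 0.118) and the neuronal tubulin gene Tubb3 (1.48, SE 0.126). The 8 largest falls were in Fbxo32 (-3.02, SE 0.112), Ypel3 (-2.20, SE 0.081), Tmem140 (-2.19, SE 0.08), C530044C16Rik (-2.17, SE 0.113), Crebrf (-2.13, SE 0.062), Pappa (-2.004, SE 0.091), Cdo1 of cysteine breakdown (-1.995, SE 0.136) and Tcp11l2 (-1.91, SE 0.071).

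Insulin in IRKO astrocytes lowered 18 of 22 autophagy initiation genes and raised 1 (camera adjusted p = 2.6e-18), lowered 11 of 18 selective autophagy genes and raised 2 (3.6e-09) and lowered 27 of 32 FOXO targets and raised 1 (4.8e-31). Gabarapl1 changed by -0.65 (SE 0.05), Map1lc3b by -0.60, Bnip3 by -0.36, Ulk2 by -0.75, Foxo3 by -0.16 and Irs2 by -0.18, and Tfeb (0.03) and Foxo1 (0.11) did not pass. ATG8 family genes fell in 6 of 16 cases and rose in 3 (camera adjusted p = 0.086). Cholesterol synthesis genes rose in 25 of 25 cases (median 1.16, camera adjusted p = 5.8e-118), fatty acid synthesis genes in 16 of 18 (1.7e-43) and ribosome biogenesis genes in 26 of 26 (4e-28). Lysosome genes fell in 22 of 30 cases (camera adjusted p = 1.3e-05, and adjusted p = 0.094 with an estimated correlation). ATF4 targets rose in 19 and fell in 3 of 27 (camera adjusted p = 9.6e-05, and adjusted p = 0.12 with an estimated correlation). Glycolysis genes rose in 11 and fell in 3 of 18 (camera adjusted p = 0.013, and adjusted p = 0.27 with an estimated correlation). Oxidative phosphorylation genes rose in 17 of 24 (camera adjusted p = 0.0019, and adjusted p = 0.36 with an estimated correlation). Early response genes fell in 17 and rose in 6 of 30 (camera adjusted p = 0.051). Microglia markers fell in 12 of 15 cases, with Cx3cr1 at -0.37 (SE 0.048) and Csf1r at -0.27 (camera adjusted p = 0.0024, and adjusted p = 0.098 with an estimated correlation). Adjusted over the list alone, 12 selective autophagy genes, 23 lysosome genes, 4 ATF4 targets and 18 early response genes fell, 18 oxidative phosphorylation genes rose, 1 fatty acid synthesis gene fell, and the other counts named here were the same.

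IGF-1 in IRKO astrocytes lowered Fbxo32 to 4.07 ± 1.07 CPM, Ulk1 to 36.1 ± 1.37 CPM and Sqstm1 to 629.9 ± 20 CPM and raised Hsd17b7 to 212.2 ± 3.35 CPM (SD, n = 4 each). It changed 8114 genes (52%, edgeR), 4195 upward and 3919 downward, with 895 and 935 past 1.5-fold. With library size alone 3829 rose and 4277 fell, and with a mean CPM of at least 1 it was 3943 and 4021. The 8 largest rises were in Hsd17b7 (2.05, SE 0.054), Mfsd2a (2.01, SE 0.053), Tuba8 (1.98, SE 0.119), Apln (1.89, SE 0.078), Rab27b (1.76, SE 0.11), Lss (1.72, SE 0.043), Tnfrsf12a (1.71, SE 0.096) and Shh, the sonic hedgehog gene (1.69, SE 0.125). The 8 largest falls were in Fbxo32 (-3.60, SE 0.121), Ypel3 (-2.51, SE 0.084), C530044C16Rik (-2.37, SE 0.117), Crebrf (-2.32, SE 0.063), Cdo1 (-2.26, SE 0.141), N4bp2l1 (-2.24, SE 0.148), Tmem140 (-2.22, SE 0.081) and Tcp11l2 (-2.21, SE 0.074). Autophagy initiation genes fell in 17 of 22 cases and rose in 1 (camera adjusted p = 1.4e-17), selective autophagy genes fell in 10 of 18 and rose in 2 (3.6e-09), and FOXO targets fell in 28 of 32 and rose in 1 (8.2e-30). Cholesterol synthesis genes rose in 25 of 25 (camera adjusted p = 3.1e-124), fatty acid synthesis genes rose in 16 of 18 and fell in 2 (2.6e-38), and ribosome biogenesis genes rose in 26 of 26 (8.7e-32). Lysosome genes fell in 24 of 30 cases (camera adjusted p = 2.7e-06, and adjusted p = 0.069 with an estimated correlation), or 26 with 1 rising when adjusted over the list alone. ATF4 targets rose in 19 and fell in 2 of 27 (camera adjusted p = 0.00012, and adjusted p = 0.14 with an estimated correlation). Glycolysis genes rose in 11 and fell in 4 of 18 (camera adjusted p = 0.013, and adjusted p = 0.29 with an estimated correlation). Oxidative phosphorylation genes rose in 19 of 24 (camera adjusted p = 0.0017, and adjusted p = 0.37 with an estimated correlation). Microglia markers fell in 11 of 15 cases (camera adjusted p = 0.0075, and adjusted p = 0.14 with an estimated correlation).

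Whether the knockout alters the response was tested as the difference between genotypes in each response. For insulin, no gene passed, Fbxo32 and Ulk1 included: edgeR called 0 of 15599 genes, with 838 at an unadjusted p under 0.05 where 780 would arise by chance, and DESeq2 also called 0. For IGF-1 edgeR called 0, with 822 at an unadjusted p under 0.05, and DESeq2 called 2, Wnt5a (0.28, DESeq2 adjusted p = 0.027) and the interferon signalling gene Stat2 (0.28, 0.037), both at an edgeR adjusted p of 0.22. Without the filter on low counts, 19 genes were called in each difference. The insulin difference called Unc5c (-0.66, edgeR adjusted p = 0.021) without IRflox vehicle replicate 1. It called Lars2 (1.43), Gm23935 (1.52), Gm24270 (1.88) and Mir6236 (1.46) without IRKO vehicle replicate 1, and Gm23935 (1.37) without IRKO insulin replicate 1. These 4 entries were grouped in the analysis as resembling ribosomal RNA, which was not tested. Their share of counts rose with the share of reads outside genes over the 24 libraries (Pearson's r 0.80). Lars2 (1.13) and Gm23935 (1.28) also passed when 5 libraries with over 20% of reads outside genes were left out, an alternative chosen after seeing the data. These genes lie outside the rule for named genes and were chosen after their values were seen. Mean reads outside genes under insulin were 16.1 ± 0.9% in floxed control and 19.4 ± 2.25% in IRKO libraries (SD, n = 4 each). Of the 24 lists, none passed for insulin (smallest camera adjusted p = 0.16). For IGF-1, the change from vehicle of interferon response genes was higher in IRKO than in floxed control (median difference of the changes 0.14, camera adjusted p = 2.8e-11, and adjusted p = 0.36 with an estimated correlation). That of fatty acid synthesis genes was also higher (median 0.05, camera adjusted p = 0.016, and adjusted p = 0.36 with an estimated correlation). That of microglia markers was lower (median -0.07, camera adjusted p = 0.00078, and adjusted p = 0.28 with an estimated correlation). Adjusted over the list alone, the change was higher for 2 interferon response genes and lower for 3 microglia markers.

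Response size was compared over the 6596 genes that changed the same way with IGF-1 in both genotypes. Each log2 change was signed by the gene's direction under IGF-1, so a change against it counts as negative. The median signed change under insulin was 0.303 in floxed control (SD between libraries 0.011, n = 4) and 0.301 in IRKO astrocytes (SD 0.013), a ratio of 0.99. Under IGF-1 it was 0.358 (SD 0.01) and 0.359 (SD 0.005), and insulin reached 0.85 of the IGF-1 size in floxed control and 0.84 in IRKO astrocytes. The genotypes differed by less than the spread between treated libraries, which leaves out vehicle error, and the ligands by more. Choosing genes by IGF-1 calls favours IGF-1 in the comparison of the ligands.

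Insulin and IGF-1 moved Fbxo32, Ulk1, Hsd17b7 and Tuba8 in the same direction, and 6317 genes changed in the same direction with both ligands in floxed control astrocytes (3385 upward, 2932 downward) against 5 in opposite directions. Those 5 were Aqp4 (0.12 under insulin, -0.18 under IGF-1), Tm4sf1 (-0.17, 0.30), Dusp4 (-0.25, 0.22), Slit2 (-0.12, 0.13) and Zswim6 (-0.16, 0.17), chosen after their values were seen. With 1 library left out, their edgeR adjusted p reached 0.065 for Aqp4 (IRflox insulin replicate 1), 0.24 for Tm4sf1, 0.15 for Dusp4 (both IRflox vehicle replicate 3), 0.097 for Slit2 (IRflox vehicle replicate 1) and 0.16 for Zswim6 (IRflox vehicle replicate 2). Independent lists of these lengths would share 1003 genes upward and 814 downward. Both comparisons used the same vehicle libraries, and unchanged groups simulated against those libraries shared 0 calls. With 0 genes called in those groups this was fixed, and it does not show how far shared libraries raise the overlap. The fold changes correlated across genes, which are not independent replicates, with r = 0.874 against 0.501 in the simulation. Their covariance was 0.152 against a simulated 0.016. With the vehicle libraries split between the comparisons (6 splits), 4608 to 4842 genes were shared and r was 0.668 to 0.718. In IRKO astrocytes 6391 genes changed in the same direction (3408 upward, 2983 downward) and 5 in opposite directions. These were Dusp6 (-0.22, 0.20), Aqp4 (0.11, -0.08), Cxcl1 (-0.20, 0.20), Slit2 (-0.18, 0.22) and Maff (-0.18, 0.16). Their edgeR adjusted p reached 0.1, 0.11 and 0.16 for Dusp6, Cxcl1 and Maff without IRKO vehicle replicate 2 and 0.071 for Aqp4 without IRKO vehicle replicate 3. Independent lists would share 1036 and 851 genes, r was 0.883 against a simulated 0.492, the covariance 0.1518 against 0.015, simulated shared calls were 0 with 0 genes called for insulin, and the split vehicle libraries gave 4682 to 4925 shared genes with r of 0.654 to 0.707.

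Between genotypes, which share no libraries, 5720 genes changed in the same direction under insulin (3116 upward, 2604 downward, against 938 and 724 for independent lists), with r = 0.767 across genes. The 3 in opposite directions were Sirt6 (-0.25 in floxed control, 0.24 in IRKO), Grin3b (-0.38, 0.50) and Gm23935 (-0.61, 0.60). Grin3b shares 32.1% of its exon length with an opposite-strand gene, so its counts are uncertain. Gm23935 is among the 4 entries grouped as resembling ribosomal RNA. Under IGF-1, 6596 genes changed in the same direction (3519 upward, 3077 downward, against 1108 and 957), with r = 0.812, and the 4 in opposite directions were Dhx58 (-0.13, 0.12), Ltb (1.29, -2.10), 4930579G24Rik (0.51, -0.58) and Sirt6 (-0.20, 0.20). These genes were chosen after their values were seen, and edgeR called none of them in the test of the difference between genotypes. For each, 1 of its calls ended without a single library, with edgeR adjusted p up to 0.14 for Sirt6 (IRKO insulin replicate 1), 0.16 for Grin3b and 0.059 for Gm23935 (both IRflox vehicle replicate 2) under insulin. Under IGF-1 it reached 0.14 for Dhx58 (IRKO IGF-1 replicate 1), 0.29 for Ltb (IRflox IGF-1 replicate 4), and 0.18 for 4930579G24Rik and 0.17 for Sirt6 (both IRflox IGF-1 replicate 2).

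IRKO and floxed control astrocytes under vehicle were compared to ask what the knockout changes before any ligand is added. Cd38, an enzyme gene of NAD breakdown (chromosome 5, 43868553 to 43912375, plus strand), rose from 18.5 ± 0.908 to 29.6 ± 1.47 CPM (SD, n = 4 each). The heat shock gene Hspa1b (chromosome 17, 34956436 to 34959238, minus strand) fell from 11.7 ± 1.29 to 5.04 ± 1.30 CPM, though its counts may be split with its near-identical copy Hspa1a. Coch fell from 20.4 ± 1.08 to 9.71 ± 1.04 CPM. Microglia markers rose in 14 of 15 cases, by a median of 0.26 on the log2 scale (camera adjusted p = 1.4e-19). Csf1r, the growth factor receptor gene of microglia (chromosome 18, 61100598 to 61132149, plus strand), rose from 267 ± 7.99 to 325 ± 15.5 CPM (n = 4 each). Cx3cr1 rose by 0.27 (SE 0.047), Laptm5 by 0.26 (SE 0.042) and Itgam by 0.30 (SE 0.04), of which Itgam shares 68.7% of its exon length with another gene. Microglia markers also stood higher in IRKO under insulin (10 of 15, camera adjusted p = 8.8e-11) and IGF-1 (8 of 15, 1.9e-08), comparisons added after seeing the data. In all, 1226 genes differed under vehicle (7.9%, edgeR), 586 upward and 640 downward, with 29 and 86 past 1.5-fold. The balance turned with library size alone as the scaling (665 upward, 534 downward) and without the filter on low counts (652, 597).

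The other largest rises under vehicle in IRKO, beside the rise of the microglia markers, were in Rlbp1 (0.65, SE 0.159), Zfp707 (0.62, SE 0.162), Mylk2 (0.61, SE 0.076), Nol3 (0.59, SE 0.142), Inha (0.57, SE 0.141), the calcium-dependent kinase gene Camk2a (0.56, SE 0.124) and Trim30c (0.53, SE 0.172). Nol3 shares 48.2% of its exon length with another gene. The call for Zfp707 was lost without IRflox vehicle replicate 3 (edgeR adjusted p = 0.064), and that for Trim30c with DESeq2 (0.056), with RLE size factors (0.051) and without most single libraries (0.058 to 0.13). Rlbp1 was at 0.051 when the 5 libraries with over 20% of reads outside genes were left out. The other largest falls were in Rspo3, a Wnt agonist gene (-1.07, SE 0.128), Bc1 (-1.04, SE 0.162), Msl3l2 (-0.92, SE 0.101), Aff2 (-0.81, SE 0.146), Prkg1 (-0.76, SE 0.096) and Xkr4 (-0.75, SE 0.158). With those 5 libraries left out, 718 genes were called, and with a microglia marker score as a covariate 76 were called, both alternatives chosen after seeing the data.

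**Figure D4:**
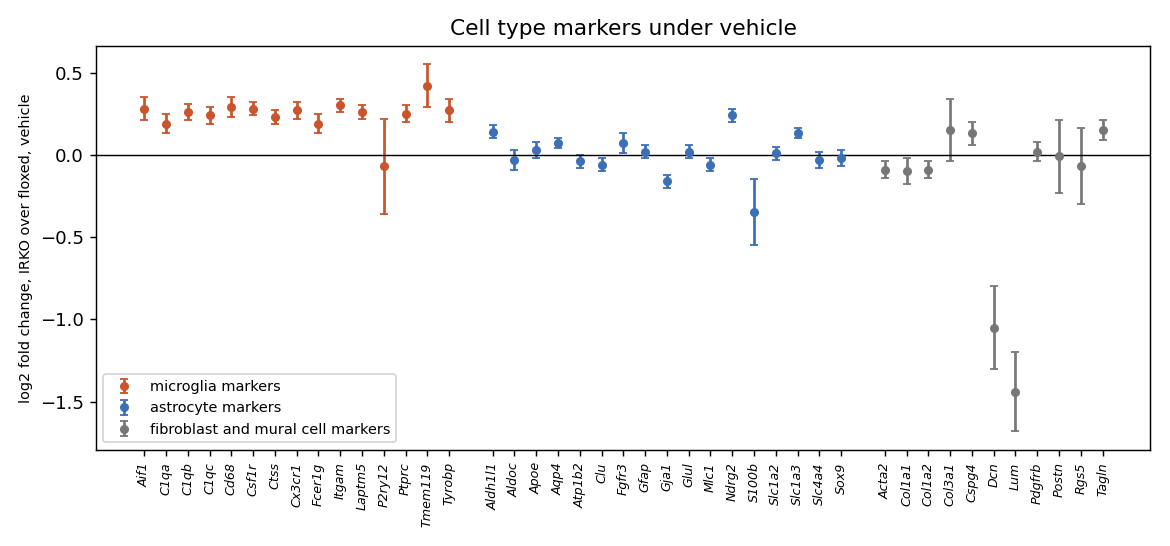
Log2 fold change ± SE of microglia, astrocyte, and fibroblast and mural cell markers, IRKO over floxed control under vehicle. The microglia markers lie above 0 near a common value, while Lum and Dcn among the fibroblast and mural cell markers lie below 0.

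Autophagy initiation and ATG8 family genes did not pass the test between genotypes under vehicle. Of 22 initiation genes edgeR called 0, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.86), and of 16 ATG8 family genes it called 0, with 1 at an unadjusted p under 0.05 (0.86), and DESeq2 called 0 in both. Of 18 selective autophagy genes 1 fell (camera adjusted p = 0.96). Ulk1 (-0.02, SE 0.053), Gabarapl1 (0.02), Map1lc3b (-0.02), Sqstm1 (-0.03), Ulk2 (-0.02), Tfeb (0.00) and Foxo1 (-0.14) did not pass, and Bnip3 (0.17) passed only without IRKO vehicle replicate 3 (edgeR adjusted p = 0.029). Lysosome genes rose in 3 of 30 cases (camera adjusted p = 0.15) and FOXO targets fell in 4 of 32 (0.66). Among the latter were Insr, Irs2 (-0.19, SE 0.038) and Foxo3 (-0.14, SE 0.038), the last lost without IRKO vehicle replicate 1 (edgeR adjusted p = 0.09) or 3 (0.074) or IRflox vehicle replicate 2 (0.058). In the insulin and IGF pathway list Igf1 rose by 0.51 (SE 0.07), Igfbp3 fell by 0.52 (SE 0.054), and 3 of 34 fell in all (camera adjusted p = 0.056). Cholesterol synthesis genes rose in 8 of 25 cases, with Hsd17b7 at 0.35 (SE 0.059) and Stard4 at 0.25 (SE 0.041), or 11 when adjusted over the list alone (camera adjusted p = 2.8e-07, and adjusted p = 0.42 with an estimated correlation). Interferon response genes fell in 5 of 27 cases, including Ifit2 (-0.29, SE 0.061) and Rsad2 (-0.33, SE 0.076), with a camera adjusted p of 0.03, and adjusted p = 0.78 with an estimated correlation. The call for Rsad2 was lost without IRflox vehicle replicate 3 (edgeR adjusted p = 0.062). Of 26 ribosome biogenesis genes 1 fell (camera adjusted p = 0.036, and adjusted p = 0.77 with an estimated correlation), and of 10 oligodendrocyte lineage markers 2 rose (0.032, and adjusted p = 0.28 with an estimated correlation). Among 17 astrocyte markers 3 rose and 1 fell (camera adjusted p = 0.69), and in the reactive astrocyte panel 5 of 34 rose and 6 fell (0.86), or 7 and 6 adjusted over the list alone. Of 11 fibroblast and mural cell markers 2 fell, Lum at -1.44 (SE 0.241) from 3.11 to 1.14 CPM and Dcn at -1.05 (SE 0.252) from 2.67 to 1.29 CPM, and the list did not pass (camera adjusted p = 0.27).

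Insulin and IGF-1 were compared directly at the same dose and time, 100 nM for 6 h. In floxed control astrocytes 404 genes differed (2.6%, edgeR), 233 higher and 171 lower under insulin than under IGF-1, of which 9 and 9 passed 1.5-fold. Ereg (chromosome 5, 91074622 to 91093646, plus strand) was at 4.76 ± 1.40 CPM under insulin and 8.502 ± 1.13 CPM under IGF-1, and the astrocyte water channel gene Aqp4 (chromosome 18, 15389496 to 15410982, minus strand) at 1233 ± 51.0 and 1004 ± 20.7 CPM (SD, n = 4 each). Genes lower under insulin were led by Ereg (-0.83, SE 0.154), Shh (-0.81, SE 0.11), the endothelial transcription factor gene Sox7 (-0.66, SE 0.122), Fosl1 (-0.60, SE 0.12) and Tnfsf11 (-0.59, SE 0.15), where Fosl1 shares 57.2% of its exon length with another gene. Genes higher under insulin were led by Ip6k3 (0.65, SE 0.167), Rhbdl3 (0.64, SE 0.081), Minar1 (0.59, SE 0.114), Arhgap8 (0.57, SE 0.144) and Lrrc75b (0.55, SE 0.113). The calls for Ip6k3, Arhgap8 and Tnfsf11 each ended without IRflox IGF-1 replicate 2 (edgeR adjusted p = 0.082, 0.098 and 0.15). They ended also without IRflox IGF-1 replicate 1 for Ip6k3 (0.1) and Arhgap8 (0.095), without IRflox insulin replicate 1 for Ip6k3 (0.068), without IRflox insulin replicate 2 for Arhgap8 (0.07) and Tnfsf11 (0.051), and without IRflox insulin replicate 4 for Tnfsf11 (0.093). The count was 250 without IRflox IGF-1 replicate 4 and 247 without IRflox insulin replicate 2.

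Cholesterol synthesis genes were lower under insulin than under IGF-1 in 12 of 25 cases in floxed control astrocytes (20 when adjusted over the list alone), with Hsd17b7 at -0.35 (SE 0.05) and Lss at -0.26 (camera adjusted p = 1.3e-20). Early response and MAPK feedback genes were lower in 9 of 30 cases and higher in 1, with Dusp6 at -0.42 (SE 0.069), Dusp4 at -0.47 (SE 0.087) and Spred3 at -0.39 (SE 0.053) (camera adjusted p = 3.7e-09), or 12 and 2 adjusted over the list alone. Interferon response genes were higher in 10 of 27 cases (20 adjusted over the list alone), with Ifit2 at 0.33 (SE 0.061) and Ifit1 at 0.28 (camera adjusted p = 2.5e-20). Astrocyte markers were higher in 4 of 17 (7 adjusted over the list alone), with Aqp4 at 0.30 (SE 0.034) and Sox9 at 0.25 (camera adjusted p = 1.3e-07), and p53 targets in 3 of 16 (6 adjusted over the list alone), with Trp53inp1 at 0.22 and Fas at 0.22 (5.1e-06). FOXO targets were higher in 2 and lower in 1 of 32, with Pik3ip1 at 0.29 (SE 0.054) (camera adjusted p = 0.0011), or 6 and 1 adjusted over the list alone, and 1 of 26 ribosome biogenesis genes was lower (3.7e-09), or 10 when adjusted over the list alone. Of 22 autophagy initiation genes edgeR called 0 (7 at an unadjusted p under 0.05) and DESeq2 0, while the list had a camera adjusted p of 0.045, and adjusted p = 0.055 with an estimated correlation. Selective autophagy (camera adjusted p = 0.0092, and adjusted p = 0.063 with an estimated correlation), circadian clock (0.0078, and adjusted p = 0.055 with an estimated correlation) and fibroblast and mural cell markers (0.045, and adjusted p = 0.32 with an estimated correlation) stood higher under insulin. Oxidative phosphorylation genes stood lower (camera adjusted p = 0.0022, and adjusted p = 0.36 with an estimated correlation). Genes of the reactive astrocyte panel were higher in 4 and lower in 5 of 34 cases (9 and 7 adjusted over the list alone), and the panel did not pass (camera adjusted p = 1).

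In IRKO astrocytes 417 genes differed between the ligands (2.7%, edgeR), 166 higher and 251 lower under insulin, of which 9 and 10 passed 1.5-fold. With library size alone as the scaling, 220 were higher and 225 lower. The 166 higher genes became 81 without IRKO insulin replicate 1 or 3, 92 without IRKO IGF-1 replicate 3 and 79 without IRKO IGF-1 replicate 4. Ereg was at 3.50 ± 0.402 CPM under insulin and 6.43 ± 1.05 CPM under IGF-1 (SD, n = 4 each). Lower under insulin were Sox7 (-0.88, SE 0.122), Ereg (-0.88, SE 0.165), the adhesion molecule gene Sele (-0.77, SE 0.178), Cemip (-0.70, SE 0.072) and Epb41l4aos (-0.66, SE 0.162). Higher were Tmem229a (0.80, SE 0.108), 4930578M01Rik (0.73, SE 0.161), Megf6 (0.69, SE 0.137), Dnajc28 (0.66, SE 0.172) and Ip6k3 (0.63, SE 0.151). Without single libraries the calls ended for Ip6k3 (IRKO IGF-1 replicate 1, edgeR adjusted p = 0.057, and IRKO insulin replicate 3, 0.079), Sele (IRKO IGF-1 replicate 4, 0.055) and Epb41l4aos (IRKO IGF-1 replicate 3, 0.075, and IRKO insulin replicate 1, 0.064). The call also ended for Dnajc28 (IRKO IGF-1 replicates 2, 3 and 4, 0.052, 0.08 and 0.089, and IRKO insulin replicates 1 and 4, 0.053 and 0.099). The count was 267 without IRKO insulin replicate 1, 277 without IRKO insulin replicate 3 and 158 without the 5 libraries with over 20% of reads outside genes, 3 of which are in these groups. In that last setting Tmem229a, Megf6, Sox7, Ereg, Cemip, Dusp6 and Aqp4 still passed, and 4930578M01Rik did not (edgeR adjusted p = 0.12).

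Among the lists in IRKO astrocytes, cholesterol synthesis genes were lower under insulin than under IGF-1 in 12 of 25 cases (22 adjusted over the list alone), with Lss at -0.31 (SE 0.041) and Hsd17b7 at -0.33 (camera adjusted p = 3.2e-30). Early response genes were lower in 9 and higher in 1 of 30 (12 and 1 adjusted over the list alone), with Dusp6 at -0.43 (SE 0.07) (camera adjusted p = 1e-08). Ribosome biogenesis genes were lower in 4 of 26 (12 adjusted over the list alone, camera adjusted p = 2.9e-11). Autophagy initiation genes were higher in 2 of 22 cases (3 adjusted over the list alone, camera adjusted p = 0.007). FOXO targets were higher in 2 and lower in 1 of 32 (6 and 1 adjusted over the list alone, camera adjusted p = 3e-04), with Pik3ip1 at 0.35 (SE 0.054). Circadian genes were higher in 3 of 16 (8 with 1 lower adjusted over the list alone, camera adjusted p = 0.00023), with Nr1d2 at 0.25 (SE 0.042). Calcoco1 was higher by 0.30 (SE 0.049) in a list of selective autophagy receptors that had a camera adjusted p of 0.024, and adjusted p = 0.13 with an estimated correlation. Astrocyte markers were higher in 3 of 17 cases, with Aqp4 at 0.19 (SE 0.034) (camera adjusted p = 7e-04, and adjusted p = 0.13 with an estimated correlation). Of 16 p53 targets 3 were higher (camera adjusted p = 0.0011, and adjusted p = 0.13 with an estimated correlation) and of 30 lysosome genes 1 was higher (0.0093, and adjusted p = 0.33 with an estimated correlation). Fatty acid synthesis genes were higher in 2 and lower in 5 of 18 (0.021, and adjusted p = 0.19 with an estimated correlation), and genes of the reactive astrocyte panel were lower in 6 of 34 (0.024, and adjusted p = 0.37 with an estimated correlation), or 7 with 1 higher adjusted over the list alone. The panel did not pass in the test of the ligand difference between genotypes (camera adjusted p = 0.083). For interferon response genes edgeR called 0 of 27 (2 at an unadjusted p under 0.05), DESeq2 called 0, and the list did not pass (camera adjusted p = 0.89). The list calls given without a second p, in the treatment, genotype and ligand comparisons, held with an estimated correlation.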

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

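The tests of explanations and the counts over other splits of the libraries in this part were chosen after the results were seen.

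Microglia markers stood higher in IRKO than in floxed control libraries under vehicle. A lower share of astrocytes would raise the markers of other cell types alike, but the weighted mean was 0.259 (SE 0.013) for microglia markers against -0.028 (SE 0.023) for fibroblast and mural cell, -0.135 (SE 0.039) for neuron and -0.052 (SE 0.051) for endothelial markers, while oligodendrocyte lineage markers, at 0.12 (SE 0.024), moved the way this explanation needs. Dilution of astrocyte RNA does not account for genes lower by over 1.5 times, as astrocyte markers gave 0.022 and -0.002. A loss of fibroblasts (Lum and Dcn fell) was not tested. A larger share of microglia stays open, since the 95% intervals of 15 of 15 markers hold their common mean. The Cre virus and receptor loss cannot be told apart here, since 0 libraries carry the Cre virus without floxed Insr. An effect of the knockout on microglia was not tested.

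The insulin response of the IRKO astrocytes was like that of the floxed control, with no gene called for the difference by edgeR or DESeq2 (838 at an unadjusted p under 0.05). Exchanged labels are argued against by Insr, which lay below each floxed control library of the same treatment in 12 of 12 IRKO libraries. The ratio of response sizes, 0.99, argues against a much weaker response spread over many genes. Without single libraries sizes spanned 0.292 to 0.309 in IRKO and 0.297 to 0.318 in floxed control. Insulin may act through remaining insulin receptor or, at 100 nM, through the IGF-1 receptor, and these cannot be told apart here: 65.7% of the Insr level remained under vehicle, counted over the whole gene, and Igf1r was present in each group.

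Liver transcripts appeared in libraries of cultured astrocytes, a signal outside the comparisons: 14 libraries held more Alb counts than the highest floxed vehicle library. RNA or reads from liver are a candidate source, since 7 other liver transcripts followed Alb over the 24 libraries (Spearman's rho 0.88, permutation p = 1e-05, the smallest that 100000 resamples can give, Benjamini-Hochberg adjusted 2e-05 over 2 relations, and Pearson's r 0.94, permutation p = 1e-05, adjusted 1e-05), with r of 0.96 without the 2 libraries farthest from the median in Alb. Whether the libraries shared a single liver source cannot be told apart from several: the ratio of Apoa4 to Alb differed between the 20 libraries with any count of either (chi-square 90.7, permutation p = 1e-05, the smallest possible), but this test covers counting error only and takes reads as independent molecules. A response of the astrocytes to insulin stays open, since Alb gave an exact two-sided permutation p of 0.29 in IRKO, where 4 libraries are set against 4, and 0.029 in floxed control.

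Some lists passed a test of the difference between genotypes itself, while single genes passed only under alternatives, among them Wnt5a and Stat2 with DESeq2 and 19 genes in each response without the filter on low counts. In the IGF-1 response, the camera adjusted p was 0.016 for fatty acid synthesis genes, 2.8e-11 for interferon response genes and 0.00078 for microglia markers. In the contrast of insulin with IGF-1, compared between genotypes as an addition after the data were seen, it was 7.5e-22 for interferon response genes and 0.037 for endothelial markers. With an estimated correlation the adjusted p was 0.36, 0.36 and 0.28 for the first 3 and 0.17 for each of the last 2.

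Single libraries stood apart from the other 3 of their group in 54 of 1104 groups of values, where chance gives about 55, since about 1 in 20 groups is marked by chance. IRKO IGF-1 replicate 2 holds 7 of them and no other library more than 3. List scores among them were 0.31 for fatty acid synthesis in IRKO IGF-1 replicate 2 and -0.26 for microglia markers in IRflox insulin replicate 3. The others are log2 CPM of single genes. In IRflox vehicle libraries these were Gabarapl1 7.42, Tnfrsf22 2.86 and Rlbp1 1.07 (replicate 2), Slc7a1 5.1 (replicate 1), Cyc1 6.24, Ifit2 8.74 and Alb -3.11 (replicate 3) and Ereg 1.48 and Apoa4 -2.53 (replicate 4). In IRflox insulin libraries they were Hmgcs1 10.51, Ifit1 8.51 and Tubb6 6.59 (replicate 1), Scd2 11.85 and Klf7 5.28 (replicate 3), and Minar1 3.05, Cxcl1 10.84 and 4930579G24Rik 1.17 (replicate 4). In IRflox IGF-1 libraries they were Slc7a1 5.95 and Zswim6 5.61 (replicate 1), Igf1 4.45 (replicate 2), Itgam 7.54, Klf7 5.04 and Apoa4 -2.54 (replicate 3), and Acaca 7.86 and Ddx21 7.95 (replicate 4). In IRKO vehicle libraries they were Inha 2.59 (replicate 1), Tcp11l2 5.64, Rspo3 2.49 and Dusp4 4.01 (replicate 2), Cyren 5.26 and Slc7a1 5.28 (replicate 3), and Spry4 4.31, Alb 2.66 and Apoa4 0.78 (replicate 4). In IRKO insulin libraries they were Scd1 9.78 and Gm24270 6.01 (replicate 2), Prkg1 3.35, Stard4 7.89 and Sesn2 6.66 (replicate 3), and Mybbp1a 8.14, Csf1r 8.07 and Rhbdl3 4.41 (replicate 4). In IRKO IGF-1 libraries they were Slc7a1 5.91, Csf1r 8.11, Itgam 7.97, Rhbdl3 3.95, Arhgap8 2.32 and Lrrc75b 3.1 (replicate 2), Foxo3 7.07 and Ldha 8.06 (replicate 3), and Spred3 6.29 and Apoa4 -2.49 (replicate 4).

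Other splits of the 8 libraries of each comparison were counted, 35 splits each, in fits of those libraries alone. These counts do not exclude chance, since the real split would rank first by chance in 1 of 35. Splits that mix the groups also carry the group difference in their spread, which lowers their counts. The labels do not say whether the libraries are separate cultures, so the splits do not exclude chance differences between cultures. The real split gave 6896 genes for insulin in floxed control against at most 0 in another split, 7748 for IGF-1 against 0, 6956 for insulin in IRKO against 2, 8063 for IGF-1 in IRKO against 0, 925 between genotypes against 5, 443 between ligands in floxed control against 52 and 592 between ligands in IRKO against 27, and in each of them 1 split, the real one, gave as many. For the differences between genotypes in the insulin and in the IGF-1 response, the real count was 0 and the highest of the others 5. Each of the 40 splits then gives as many whatever the data, so these splits decide nothing about chance.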

How the results depend on the processing

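The alternatives were chosen before the data were examined, except leaving out the 5 libraries with over 20% of reads outside genes, the microglia marker covariate and the floor of mean log2 CPM 2, which were chosen after the results were seen. Where a value moved, the cause was not tested unless stated.

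The counts for insulin or IGF-1 against vehicle stayed within 1.5 times under each alternative, and with RLE factors, library size alone, a mean CPM of at least 1 or the groups compared alone so did each other count. RLE or library size scaling shifted the median of all genes by at most 0.027 on the log2 scale. DESeq2 called 6864, 7736, 6943 and 7812 genes for insulin and IGF-1 in floxed control and in IRKO astrocytes, 1260 between genotypes, 471 and 504 between ligands, and 0 and 2 for the differences between genotypes. The balance of rises and falls also turned in settings the report does not name: for IGF-1 in IRKO with the groups compared alone (4002 up, 4061 down) and without the low-count filter (3951, 3953), between genotypes with the groups compared alone (468, 457) and with the microglia covariate (41, 35), and without single libraries. These were IRflox insulin replicate 1 (3238, 3492 for insulin), IRflox IGF-1 replicate 1 (3759, 3788 for IGF-1), IRKO insulin replicate 3 (3263, 3371 for insulin), IRKO IGF-1 replicate 2 (3842, 3859 for IGF-1), IRKO vehicle replicate 4 (3450, 3475 for insulin, 3891, 3892 for IGF-1 and 590, 568 between genotypes) and IRKO vehicle replicate 1 (476, 471 between genotypes). Between ligands in floxed control, 307 genes were higher and 296 lower without the low-count filter. Without that filter the differences in the insulin and IGF-1 responses held 19 and 19 genes. Without the 5 libraries, the genotype count fell to 718, the ligand count in IRKO to 158, and the insulin difference rose to 2, in fits with fewer samples. With the microglia covariate 76 genes were called between genotypes, 57 of them among the 1226. The median standard error rose from 0.075 to 0.164, and the median absolute change of the 1226 genes went from 0.246 to 0.231. Medians of absolute changes do not follow single genes, and the score itself differs between genotypes. Whether wider errors or a removed difference ended the calls is therefore not settled. Ctsd (-0.029), Pkm (-0.054) and Cd14 (-0.010) turned direction there, where Ctsd is uncertain since it shares 34.4% of its exon length with another gene. Leaving out 1 library at a time gave 6448 to 6963 genes for insulin and 7300 to 7745 for IGF-1 in floxed control, 6634 to 6925 and 7554 to 7783 in IRKO, 931 to 1158 between genotypes, 247 to 424 and 267 to 402 between ligands in floxed control and IRKO, 0 to 4 for the insulin difference and 0 to 0 for the IGF-1 difference. The insulin difference held 1 gene without IRflox vehicle replicate 1, 4 without IRKO vehicle replicate 1 and 1 without IRKO insulin replicate 1. The ligand count of the floxed control moved by more than 1.5 times without IRflox insulin replicate 2 (247) and IRflox IGF-1 replicate 4 (250), and that of IRKO without insulin replicate 1 (267) and 3 (277).

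Replicate numbers are shared between groups. Over 60 same-numbered pairs the deviations from the group means correlated by 0.006 on average (-0.154 to 0.152, over 0.1 in 5), and 2 of 24 libraries correlated best with their own number, so the numbers do not pair the samples. With the replicate block the counts were 7115, 7917, 7229, 8089, 1216, 411, 428, 0 and 0, in the order of insulin and IGF-1 in floxed control, the same in IRKO, genotype, ligands in floxed control, ligands in IRKO, and the 2 differences. The block moved 1 list over the threshold, early response genes under insulin in IRKO (camera adjusted p = 0.046).

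The response size under insulin and IGF-1 was 0.329 and 0.389 in floxed control and 0.327 and 0.389 in IRKO over genes called at an adjusted p under 0.01, and 0.383, 0.452, 0.376 and 0.451 as a mean over genes. Without single libraries it spanned 0.297 to 0.318 and 0.356 to 0.375 in floxed control and 0.292 to 0.309 and 0.356 to 0.368 in IRKO. The lower Insr level of IRKO kept its direction and call under RLE, library size, DESeq2 and the block, and the numbers of genes shared by the ligands stayed within 1.5 times under their alternatives. With DESeq2, over 25053 genes without the low-count filter, r between the ligands was 0.602 and the covariance 0.3523 in floxed control, and 0.609 and 0.3471 in IRKO.

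With an estimated correlation, 38 list calls were lost, given as camera adjusted p. Insulin in floxed control: lysosome 0.092, glycolysis 0.21, ATF4 targets 0.096, oxidative phosphorylation 0.42, microglia 0.21. IGF-1 in floxed control: lysosome 0.13, glycolysis 0.21, ATF4 targets 0.15, oxidative phosphorylation 0.26, p53 targets 0.26. Insulin in IRKO: lysosome 0.094, glycolysis 0.27, ATF4 targets 0.12, oxidative phosphorylation 0.36, microglia 0.098. IGF-1 in IRKO: lysosome 0.069, glycolysis 0.29, ATF4 targets 0.14, oxidative phosphorylation 0.37, microglia 0.14. Genotype: cholesterol 0.42, ribosome biogenesis 0.77, interferon 0.78, oligodendrocyte 0.28. Ligands in floxed control: autophagy initiation 0.055, selective autophagy 0.063, oxidative phosphorylation 0.36, circadian 0.055, fibroblast 0.32. Ligands in IRKO: selective autophagy 0.13, lysosome 0.33, fatty acid 0.19, p53 targets 0.13, reactive astrocyte 0.37, astrocyte 0.13. IGF-1 difference: fatty acid 0.36, interferon 0.36, microglia 0.28.

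fry, which does not compare a list with other genes, called 32 further lists. Insulin in floxed control: ATG8 1e-05, early response 0.0018, insulin pathway 1.7e-06, circadian 0.001, p53 targets 0.023, interferon 0.022, oligodendrocyte 0.00033, neuron 2.9e-06. IGF-1 in floxed control: ATG8 2e-07, insulin pathway 3.3e-06, circadian 1e-06, astrocyte 8.3e-05, microglia 5.9e-05, oligodendrocyte 3.1e-05, neuron 1.3e-07, endothelial 0.0044. Insulin in IRKO: ATG8 1e-06, early response 7.8e-05, insulin pathway 1.3e-06, reactive astrocyte 0.014, oligodendrocyte 0.0015, neuron 5e-05, endothelial 0.0079. IGF-1 in IRKO: ATG8 1e-07, cell cycle 0.015, insulin pathway 7.1e-05, circadian 1.2e-05, p53 targets 8.2e-05, astrocyte 0.0034, oligodendrocyte 0.00019, neuron 6.9e-07. Genotype: insulin pathway 0.0055. It did not call 9 that camera did: ribosome biogenesis 0.17 and interferon 0.38 between genotypes, oxidative phosphorylation 0.18 and fibroblast 0.13 between ligands in floxed control, lysosome 0.05 and reactive astrocyte 0.18 between ligands in IRKO, and fatty acid 0.15, interferon 0.5 and microglia 0.15 in the IGF-1 difference. RLE factors moved the insulin pathway list, which holds Insr, to a camera adjusted p of 0.045 between genotypes.

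For the named genes, 1062 results were recomputed 19759 times: 565 calls were lost, 124 gained and 3 turned direction, and 148 results lost and 50 gained a call at least once. DESeq2 gave no adjusted p in 21 further cases. For insulin in floxed control, simulated with 200 changed genes, edgeR recovered 45.4% of 1.2-fold and 88.5% of 2-fold changes. The data had 7131 calls, so recovery may differ.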

Other observations

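The families below and the correlation were chosen after the data were examined, and their tests are exploratory.

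Other gene families moved with insulin in floxed control astrocytes. Of 14 tubulin genes 13 rose, by a median of 0.74 on the log2 scale (camera adjusted p = 2.7e-26 over 14 families), among them Tubb6 (1.16, SE 0.06), Tubb5 (0.72, SE 0.04) and Tuba1b (0.71, SE 0.05), and 13 rose in IRKO astrocytes (1.9e-26). Tuba1b is uncertain, since it shares 22.7% of its exon length with another gene. All 7 genes of the CCT chaperonin, which folds tubulin and actin, rose in floxed control astrocytes (median 0.40, camera adjusted p = 9.7e-08), for example Cct6a (0.56, SE 0.04). Proteasome genes rose in 34 of 38 cases, with Psmc3 at 0.27 (SE 0.04) (camera adjusted p = 8.2e-08, and adjusted p = 0.1 with an estimated correlation). RNA polymerase I subunit genes rose in 5 of 5 cases, with Polr1b at 0.81 (SE 0.07) (camera adjusted p = 3e-05), and translation initiation factor genes rose in 32 and fell in 6 of 54 (3.3e-06, and adjusted p = 0.043 with an estimated correlation). All 5 Ypel genes fell, including Ypel2 (-1.13, SE 0.12) and Ypel4 (-0.90, SE 0.15) (camera adjusted p = 2.4e-07). Of 14 Klf transcription factor genes 9 fell and none rose, with Klf11 at -1.40 (SE 0.13) and Klf7 at -0.55 (SE 0.06) (camera adjusted p = 2.5e-05). Among the stress-response sestrins Sesn3 fell by 0.92 (SE 0.04) and Sesn1 by 0.31 on the log2 scale, and Sesn2 rose by 0.23 (camera adjusted p = 0.015 for the family). Heat shock and DnaJ genes rose in 26 and fell in 8 of 64 (camera adjusted p = 9.5e-05), and in 25 and 6 in IRKO astrocytes (3e-04). Dusp phosphatase genes rose in 4 and fell in 2 of 19 (camera adjusted p = 0.85), vacuolar ATPase genes rose in 3 and fell in 6 of 18 (0.16), amino acid carriers rose in 5 and fell in 7 of 19 (0.85), and collagens rose in 7 and fell in 8 of 37 (0.91). The 2 measured histone genes did not pass as a family (camera adjusted p = 0.85).

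Heat shock and DnaJ genes differed between genotypes. Under vehicle 12 of 64 were lower in IRKO and none higher (camera adjusted p = 1.6e-04, and adjusted p = 0.025 with an estimated correlation), with Hspb1 at -0.66, Hspa8 at -0.33 (SE 0.04) and Hsph1 at -0.29 (SE 0.05) besides Hspa1b at -1.22. The call for Hspb1 ended without IRflox vehicle replicate 3 (edgeR adjusted p = 0.054) or IRKO vehicle replicate 1 (0.051). Over all treatments together 19 were lower and 1 higher (camera adjusted p = 1.6e-06). CCT chaperonin genes were then lower in 6 of 7 cases and translation initiation factor genes lower in 13 and higher in 2 of 54 (camera adjusted p = 0.02 and 0.02, and adjusted p = 0.51 with an estimated correlation for each). Hspa1a and Hspa1b are near-identical copies, and their split of reads is uncertain.

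Gm23935, Lars2, Mir6236 and Gm24270 were grouped as resembling ribosomal RNA, which was not tested. They passed for the genotype difference in the insulin response without IRKO vehicle replicate 1. Their share of counts rose with the share of reads outside genes over the 24 libraries. Pearson's r was 0.80 (permutation p = 1e-05, the smallest that 100000 resamples can give, and 1e-05 after Benjamini-Hochberg adjustment over 2 relations) and Spearman's rho 0.73 (permutation p = 1e-04, adjusted 1e-04). Without the 2 libraries farthest from the median in reads outside genes, r was 0.75 and rho 0.66. Both measures are shares of the same libraries, and the relation was not tested within groups, which hold 4 libraries each.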
